A study of Mus musculus with 12 samples.

How the data were processed

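RNA from dorsal root ganglia of C57BL/6 mice was sequenced as paired reads of total RNA, per the labels' protocols, in 6 control and 6 DAAO libraries. The deposited table held whole-number read counts per gene for all 12 libraries, not normalised, with gene names, identifiers and positions. HISAT2 2.0.5, FastQC and DESeq2 1.20.0 and the builds GRCm38 and mm10 are named per the submitters' processing notes. The counting program, its strand setting, its treatment of reads that match several genes and the annotation release are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and reads shared by near-identical copies can be split between them, so such genes were named as uncertain.

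The table held 54532 genes, of which 31995 had at least 1 count. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 17002 genes holding at least 99.7% of the counts of each library. Of the gene names 103 occurred more than once in the table and 4 did among the genes tested; both entries of Aldoa were counted in its list. Groups were taken from the labels, and the 12 libraries were compared as 6 DAAO against 6 control with no other term. Counts were scaled with TMM factors and tested with edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are DAAO minus control, and their SE is the absolute log2 fold change divided by the square root of the F statistic. CPM (counts scaled to a common library size) were normalised by TMM and are given as mean ± SD over 6 libraries, except that the CPM of Xist and the Y-linked genes were scaled by library totals alone.

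The design, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The 52 lists covered the cell types of the ganglion, tissues that adjoin it, and pathways of oxidative stress, metabolism, injury and excitability; 739 of their 744 symbols were in the table, and 50 lists had at least 4 members tested. Lists were tested with camera of limma 3.58.1, which asks whether the members rank above or below other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 50 lists. Named genes were the label genes Cdh5, Dao and Gt(ROSA)26Sor, then, among genes that passed with an average log2 CPM of at least 1, the 8 largest rises, the 8 largest falls and the 4 smallest p-values in each direction, leaving out unnamed predicted genes and pseudogenes, and up to 4 members with the smallest p of each list described. Genes outside this rule are said to have been chosen after their values were seen, apart from list members that passed adjusted over the list alone. A list's level per library is the mean over its members of the log2 CPM centred over the libraries (prior count 2), and 10 such levels or differences of levels, chosen after seeing the data, were compared with exact two-sided permutation tests over all 924 splits, adjusted over the 10.

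The test was tested on simulated data made from the means and library sizes of the real libraries, with 16418 genes passing the filter. It called 8 of 67 genes changed 1.5-fold, 38 of 67 changed 2-fold and 53 of 66 changed 4-fold, all with the right sign. Of 105 simulated calls 3.81% were false with edgeR, against 13.4% of 142 with DESeq2 and 3.26% of 92 with limma-voom. No gene and no list was called when no change was simulated. Simulated genes varied independently of each other, with the same spread in both groups. The simulation therefore does not measure false calls from correlated genes, from tissue differences or from the unequal spread of the real groups.

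The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without sample weights, other filters and thresholds, the replicate number as a block, terms for sex and for tissue levels, 1 surrogate variable from sva 3.50.0, tables without mitochondrial or non-coding genes, and each library left out in turn. Terms for spinal cord and fibroblast levels and fits without several control libraries were added after seeing the data. For 100 of the 462 splits of the libraries into equal groups the tests were run again.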

Results

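Dorsal root ganglia, which hold the cell bodies of the sensory neurons of the trunk and limbs, were taken from C57BL/6 mice, and their total RNA was sequenced as 12 libraries. Both groups received D-alanine. The 6 control libraries came from mice with Cdh5-Cre, a recombinase under the promoter of vascular endothelial cadherin. The 6 DAAO libraries came from mice labelled as DAAO transgenic with Cdh5; D-amino acid oxidase is an enzyme that releases hydrogen peroxide when it oxidises D-alanine. The genotype label of the DAAO mice does not name Cre, which only their sample and column names carry, so a difference in Cre between the groups cannot be ruled out from the labels. The comparison asked which transcripts of the ganglia differed between these 2 genotypes. Each library held between 13227518 and 23884927 counts over 54532 genes, and the difference in totals between the groups was within their spread (n = 6 per group; exact permutation p = 0.859, two-sided). The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples.

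The ganglia of DAAO mice held more transcripts of a list of non-myelinating and repair Schwann cell markers, here the repair Schwann cell list. They held fewer of a list of proprioceptor and large-diameter neuron markers, here the proprioceptor list. Proprioceptors are the large sensory neurons that report limb position. Macrophage markers and nerve injury genes also ranked higher, but not with an estimated correlation between genes (adjusted p = 0.313 for each). Tnc, the matrix glycoprotein tenascin-C, rose from 2.69 ± 0.900 to 67.2 ± 25.2 CPM (normalised counts scaled to a common library size), and Atf3, a transcription factor induced in injured sensory neurons, rose from 15.7 ± 4.83 to 69.8 ± 19.1 (mean ± SD, n = 6). Runx3, a transcription factor of proprioceptors, fell from 6.60 ± 2.26 to 1.53 ± 0.475 CPM. The endothelial marker list, which holds the gene whose promoter drove Cre, did not change as a group.

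Of 17002 genes tested, 128 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 86 higher and 42 lower in DAAO. At least 2-fold changes made up 73 of them, 56 higher and 17 lower. In all 128 the 6 of 6 DAAO libraries lay beyond the control median in the direction of the call, and in 105 the groups did not overlap. Over all genes tested the groups did not overlap in 246, or 1.45%, where chance gives 0.216%. An unadjusted p under 0.05 was reached by 1753 genes. The count moved by more than 1.5 times without control 1 (80), 2 (322) or 5 (77) or DAAO 1 (78), 2 (65), 3 (73) or 6 (61). It was 370 with DESeq2 and 648 without controls 2 and 6, an alternative chosen after seeing the data.

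**Figure D1:**
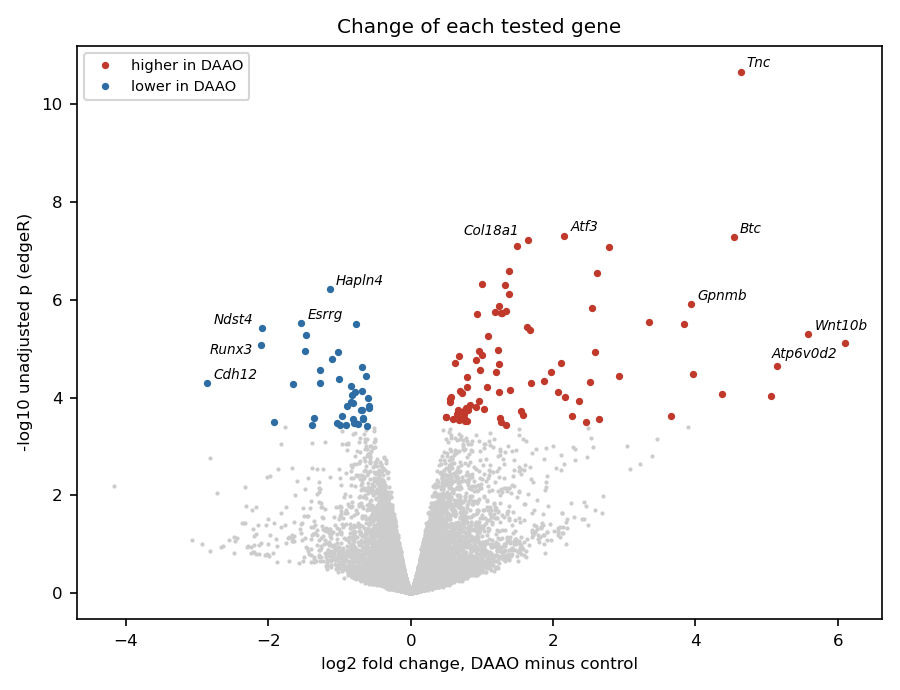
Log2 fold change of each of 17002 genes (horizontal axis, DAAO minus control) against the negative log10 of its unadjusted p by edgeR (vertical axis). The 86 genes that rose are red, the 42 that fell are blue, and Tnc stands highest.

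The control libraries varied more than the DAAO libraries. The common biological coefficient of variation was 44.3% in controls and 27.3% in DAAO, and the median correlation of log2 CPM was 0.919 between control libraries, 0.960 between DAAO libraries and 0.931 between the groups. The first principal component held 20.6% of the variance and the second held 16.2%. Mitochondrially encoded transcripts took 5.50% ± 1.61 of counts in controls, with 7.44% in control 2 and 7.65% in control 6, against 4.27% ± 0.743 in DAAO (SD, n = 6; exact permutation p = 0.145, two-sided). Skeletal muscle actin (Acta1) reached 729 CPM in the control libraries, with a lowest value of 4.32, and 148 in the DAAO libraries, and the oligodendrocyte transcript Mobp ranged from 11.4 to 2097 and from 75.0 to 572. Transcripts of Xist and of 4 Y-linked genes were both above 10 CPM in 5 libraries, controls 1 and 2 and DAAO 1, 2 and 6. In control 1 they stood at 105 and 85.0 CPM. These 5 libraries may hold RNA of more than 1 animal, so n = 6 counts libraries, not animals. The 12 libraries all differed from each other by more than sampling noise, with a smallest chi-square per degree of freedom of 19.5 over 66 pairs.

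The genes of the labels were examined first. Cdh5 (ENSMUSG00000031871; chromosome 8, 104101625 to 104144511, all positions on build GRCm38) stood at 21.5 ± 6.41 CPM in controls and 23.4 ± 8.48 in DAAO, a log2 fold change of 0.12 ± 0.24 (SE, adjusted p = 0.937). The mouse gene Dao, which encodes the animal's own D-amino acid oxidase, stood at 1.09 ± 1.98 and 1.10 ± 1.05 (adjusted p = 0.999). Whether transgene reads were counted under any gene is not given in the sources used here, so neither gene tests for the transgene. Gt(ROSA)26Sor, a transcript of a locus often used for transgenes, had 14.4 ± 5.27 and 30.8 ± 10.2 CPM. Its log2 fold change of 1.09 ± 0.26 did not pass (adjusted p = 0.0789), although 6 of 6 DAAO libraries lay above the control median. It overlaps Thumpd3 on the other strand, whose log2 fold change went the other way (-0.52, adjusted p = 0.146). The strand setting of the counting is not given in the sources used here.

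The largest rise by log2 fold change among the named genes was that of Atp6v0d2, a subunit of the vacuolar proton pump (6.11 ± 0.84 SE, adjusted p = 0.00421), from 0.261 ± 0.452 to 19.4 ± 13.3 CPM. The next were Wnt10b, a Wnt ligand (5.58 ± 0.81, adjusted p = 0.00304), and Mmp12, the macrophage elastase (5.15 ± 0.83, adjusted p = 0.00854). Over the 6 control libraries together these 3 genes had 31, 20 and 29 counts, and over the 6 DAAO libraries 2082, 967 and 1039. Tnc (ENSMUSG00000028364; chromosome 4, 63959785 to 64047015) rose by 4.63 ± 0.29 (adjusted p = 3.62e-07), the smallest p of all genes. Btc, which encodes the growth factor betacellulin, rose by 4.54 ± 0.46 (adjusted p = 0.000235), from 0.934 ± 0.573 to 22.5 ± 7.81 CPM. Clec4d, a lectin of myeloid cells, Ucn2, the peptide urocortin 2, and Gpnmb, a glycoprotein of phagocytes, rose by 4.38 ± 0.85, 3.97 ± 0.71 and 3.94 ± 0.44 (adjusted p = 0.0202, 0.0109 and 0.00160). The call of Clec4d was lost without DAAO 2, 3 or 6 (adjusted p from 0.0537 to 0.0789). Col18a1, the collagen XVIII chain (ENSMUSG00000001435; chromosome 10, 77052178 to 77166548), rose by 1.64 ± 0.18 (adjusted p = 0.000235), from 29.4 ± 7.39 to 91.6 ± 19.5 CPM. It overlaps Slc19a1 on the other strand, whose log2 fold change was 0.12 (adjusted p = 0.904).

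**Figure D2:**
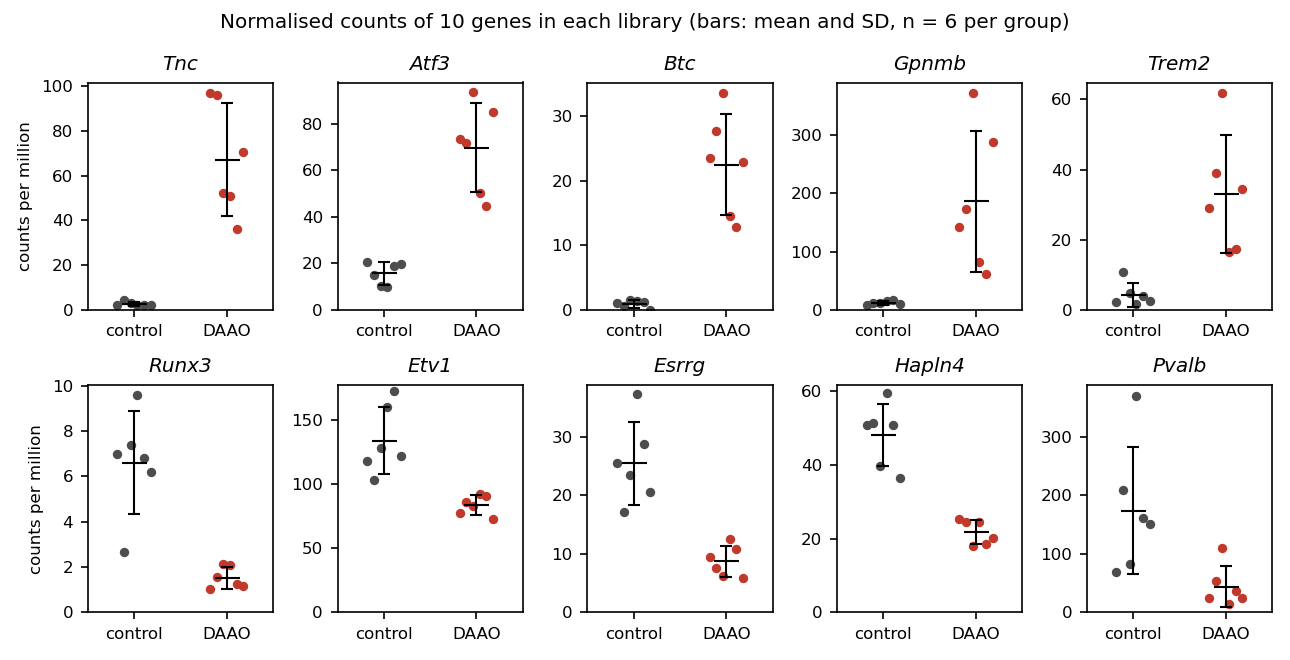
Normalised CPM of 10 genes (vertical axes) in each of the 6 control and 6 DAAO libraries, with bars at the mean and SD. The 5 genes of the upper row were higher in every DAAO library than in any control library, and of the lower row only Pvalb did not pass the test.

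The largest fall was that of Cdh12, a cadherin, with a log2 fold change of -2.87 ± 0.53 (SE, adjusted p = 0.0146), from 4.33 ± 2.68 to 0.586 ± 0.269 CPM. Runx3 (ENSMUSG00000070691; chromosome 4, 135120652 to 135177990) and Ndst4, a heparan sulfate-modifying enzyme, followed with -2.10 ± 0.33 and -2.09 ± 0.30 (adjusted p = 0.00455 and 0.00247). Wdr72 and Vstm2b fell by 1.93 and 1.65 on the log2 scale (adjusted p = 0.0450 and 0.0148). The call of Wdr72 was lost when any library other than control 2 or DAAO 3 was left out (adjusted p from 0.0624 to 0.133). Esrrg, an orphan nuclear receptor (ENSMUSG00000026610; chromosome 1, 187608791 to 188214885), fell from 25.5 ± 7.05 to 8.74 ± 2.67 CPM, a log2 fold change of -1.54 ± 0.22 (adjusted p = 0.00217). Sh3bgr and Clec2l fell by 1.48 and 1.47 (adjusted p = 0.00530 and 0.00305). Hapln4, a link protein of perineuronal matrix (ENSMUSG00000007594; chromosome 8, 70083457 to 70090862), had the smallest p of the lower genes, with -1.14 ± 0.15 (adjusted p = 0.000925). Glrb, the beta subunit of the glycine receptor, fell from 208 ± 18.3 to 123 ± 15.3 CPM (-0.76 ± 0.11, adjusted p = 0.00217).

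Markers of proprioceptors and large-diameter neurons fell together. All 9 tested members had a negative log2 fold change, with a median of -0.68, and the list ranked below other genes by camera (adjusted p = 1.60e-11; adjusted p = 0.0171 with an estimated correlation). Over all genes tested 3 members fell, Runx3, Etv1 and Whrn, and 7 of 9 did when adjusted over the list alone. Etv1 fell from 134 ± 26.4 to 83.6 ± 7.51 CPM (-0.68 ± 0.13 SE, adjusted p = 0.0185), a call lost without DAAO 1, 2 or 6 (adjusted p from 0.0509 to 0.0747). Whrn had -0.82 ± 0.18 (adjusted p = 0.0418), a call lost when any library but control 2, control 5 or DAAO 1 was left out (adjusted p from 0.0703 to 0.134). Pvalb, the calcium-binding protein parvalbumin, stood at 174 ± 109 and 44.2 ± 34.8 and did not pass (adjusted p = 0.175). Pvalb is also abundant in fast skeletal muscle, and the 11 tested muscle markers had a median log2 fold change of -2.22 (camera adjusted p = 0.000564; adjusted p = 0.643 with an estimated correlation), or -1.19 without control 4. None of them changed over all genes tested, and Pvalb passed adjusted over the list alone. The mean centred log2 level of the proprioceptor list per library was 0.42 ± 0.33 in controls and -0.42 ± 0.17 in DAAO (SD, n = 6; exact permutation p = 0.00216, two-sided, the smallest the 924 splits allow; 0.00722 adjusted over 10 such comparisons). Without Pvalb and Spp1 it was 0.36 ± 0.41 and -0.36 ± 0.10 (exact permutation p = 0.00433, two-sided, adjusted 0.00866).

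Markers of 3 other classes of sensory neuron did not change as groups. The median log2 fold change was 0.12 for 8 peptidergic nociceptor markers, 0.03 for 15 markers of non-peptidergic nociceptors and pruriceptors and 0.00 for 5 markers of C-fibre low-threshold mechanoreceptors (camera adjusted p = 0.536, 0.691 and 0.517), and no member of these lists changed. The per-library difference between the proprioceptor list and the mean of these 3 lists was lower in DAAO by a tested margin (-0.98 ± 0.17 SE, n = 6 per group; exact permutation p = 0.00216, two-sided, the smallest possible; adjusted 0.00722). The 9 markers of A-fibre low-threshold mechanoreceptors, which are not among these 3 lists, ranked lower with a median of -0.07 (camera adjusted p = 0.0168; adjusted p = 0.313 with an estimated correlation; 0.0796 without control 4 and 0.0701 without DAAO 3). That median was -0.04 without control 4 or DAAO 3, -0.12 without control 2 or 5, -0.13 without control 6 or DAAO 2 and -0.17 without DAAO 4. Pan-neuronal or tissue levels as terms ended the call in 4 alternatives, and so did leaving out controls 2, 4 and 6 (from 0.0501 to 0.122). The median stayed at -0.07 with the pan-neuronal level and was -0.21 without controls 2, 4 and 6. It lay between -0.04 and 0.01 in the fits with the fibroblast level. Of them Calb1, which encodes calbindin, fell by 0.83 on the log2 scale (adjusted p = 0.0202, lost without DAAO 1, 2, 3 or 6, from 0.0583 to 0.0747). Shox2, which overlaps Rsrc1, fell by 1.38 (adjusted p = 0.0489, lost when any library but control 2 or DAAO 4 was left out, from 0.0618 to 0.139). The same 2 passed adjusted over the list alone. The 17 pan-neuronal markers had a median of -0.19 (camera adjusted p = 0.00242; adjusted p = 0.643 with an estimated correlation; 0.0662 without control 6), and 1 of them, Snap25, fell (-0.61 ± 0.14 SE, adjusted p = 0.0498), a call lost when any library but control 2 or DAAO 4 was left out (from 0.0547 to 0.166). The pan-neuronal median was -0.12 without control 4 or DAAO 2, and its call was lost in 4 alternatives, among them the fibroblast level as a term (from 0.0561 to 0.652). Another was the list's own level as a term, where the loss was fixed in advance. With the pan-neuronal level as a term the peptidergic and C-fibre lists passed as higher (0.21 and 0.17, adjusted p = 0.0436 and 0.0432).

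Genes of excitability and axons moved little as groups. Voltage-gated sodium, potassium and calcium channel lists had medians of -0.10, -0.02 and 0.16 (camera adjusted p = 0.169, 0.251 and 0.301); without control 2 the first 2 passed, with adjusted p of 0.00674 and 0.000344 and medians of -0.20 and -0.12. Scn1a, a sodium channel, fell by 0.70 (adjusted p = 0.0330), a call lost when any library but control 1, control 2 or DAAO 4 was left out (from 0.0511 to 0.117). The synaptic vesicle list had a median of -0.15 (camera adjusted p = 0.0580), and passed without control 2, 5 or 6 or DAAO 2, 4 or 5 (from 0.00283 to 0.0494). Its member Vamp1, a vesicle fusion protein, fell by 0.60 (adjusted p = 0.0231), a call lost without control 1, 3 or 4 or DAAO 2, 3, 4 or 6 (from 0.0532 to 0.0928). The axonal transport and cytoskeleton list had a median of -0.08 (camera adjusted p = 0.0252; adjusted p = 0.643 with an estimated correlation), a call lost without control 1 or 4 or DAAO 1 or 3 (adjusted p of 0.114, 0.373, 0.0578 and 0.0832). Its median was -0.06 without control 1 or DAAO 3, -0.20 without control 2, -0.04 without control 4 and -0.14 without control 5. The call was also lost with pan-neuronal or tissue levels or a surrogate variable as terms, with medians from -0.03 to 0.07 (from 0.112 to 0.724).

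**Figure D3:**
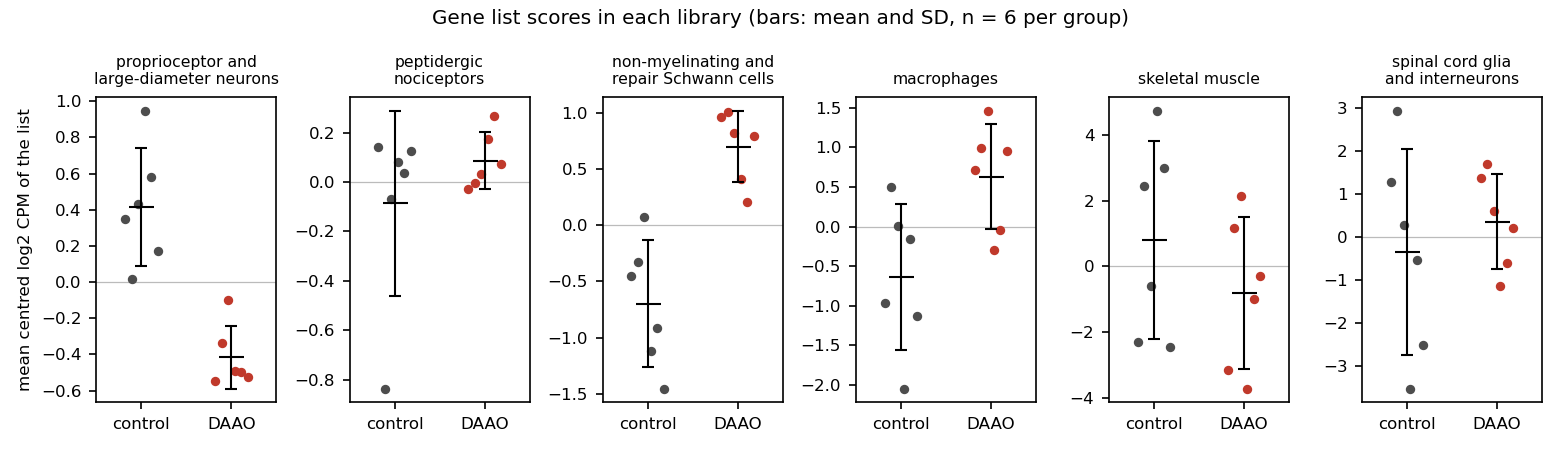
Mean centred log2 CPM of 6 gene lists (vertical axes) in each of the 6 control and 6 DAAO libraries, with bars at the mean and SD. Every DAAO library lay below every control library for the proprioceptor list (means 0.42 and -0.42), and above every control library for the repair Schwann cell list, while the muscle and spinal cord lists spread over several log2 units in both groups.

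Markers of Schwann cells, the glia that wrap axons, were tested as 2 lists, and whole ganglia do not show which cells held them. The 12 members of the non-myelinating and repair Schwann cell list had a median log2 fold change of 0.49 and a mean of 1.02. The change was positive in 9 members and negative in 3. They ranked above other genes by camera (adjusted p = 3.89e-08, or 0.00560 with an estimated correlation). Without control 2 the median was 1.31. Of these members 3 rose, Btc, Runx2 and Sox2, and 4 did adjusted over the list alone, with Gdnf, a neurotrophic factor (2.71, adjusted p = 0.276 over all genes). Runx2, a transcription factor, rose from 7.30 ± 2.64 to 23.2 ± 6.12 CPM (1.67 ± 0.25 SE, adjusted p = 0.00260), and Sox2 from 23.7 ± 8.08 to 49.6 ± 8.15 (1.07 ± 0.20, adjusted p = 0.0164), a call lost without DAAO 3 or 6 (0.0608 and 0.0519). Runx2 and Sox2 lie within or across other transcribed genes, Supt3 and Sox2ot, so part of their counts is uncertain. The mean centred log2 level of the list per library was -0.70 ± 0.56 in controls and 0.70 ± 0.32 in DAAO (SD, n = 6; exact permutation p = 0.00216, two-sided, the smallest possible; adjusted 0.00722). All 15 myelinating Schwann cell markers had negative log2 fold changes, with a median of -0.50 (camera adjusted p = 1.56e-06; adjusted p = 0.465 with an estimated correlation), or -0.27 without control 2. None fell over all genes tested, and 6 did adjusted over the list alone, led by Drp2 and Cldn19. As small a camera p for the myelinating list came in 19 of 100 splits of the libraries, the real one included. It was called in 73 of the other splits, so chance cannot be excluded for this list by that count. The 5 satellite glia markers had a median of -0.43 (camera adjusted p = 0.0130; adjusted p = 0.313 with an estimated correlation; 0.114 without control 2, where the median was -0.13). None changed over all genes, and Fabp7 (-0.73, adjusted p = 0.0807) passed adjusted over the list alone.

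The nerve injury list, of genes that sensory neurons raise after axon damage, had a median of 0.16 over 14 members (camera adjusted p = 0.000690; adjusted p = 0.313 with an estimated correlation). That median moved with single libraries. It was 0.26, 0.05, 0.02 and 0.02 without controls 2, 3, 4 and 5, and 0.09, 0.08 and 0.11 without DAAO 1, 5 and 6. The change was positive in 9 members and negative in 5, and whole ganglia do not show which cells held these transcripts. The groups overlapped in the level of this list per library, which was highest in control 1 (0.46; DAAO libraries from -0.29 to 0.41). Of its members Atf3 (ENSMUSG00000026628; chromosome 1, 191170296 to 191218039) rose by 2.16 ± 0.23 (SE, adjusted p = 0.000235) and Jun, its partner transcription factor, by 0.62 ± 0.10 (adjusted p = 0.00789). Gadd45a passed only adjusted over the list alone (0.92, adjusted p = 0.0669 over all genes). The immediate early genes had a median of 0.36 over 12 members (camera adjusted p = 0.0108; adjusted p = 0.6249 with an estimated correlation; 0.0701 without DAAO 3), or 0.23 without control 6. With pan-neuronal, spinal cord or fibroblast levels as terms the call was lost, with medians from 0.07 to 0.29 (from 0.0577 to 0.360). None of them changed over all genes tested, and Fos (1.52, adjusted p = 0.0554) and Junb (0.80, adjusted p = 0.196) passed adjusted over the list alone.

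Macrophage markers were higher in DAAO in 18 of 20 cases, with a median log2 fold change of 1.06 (camera adjusted p = 2.36e-12; adjusted p = 0.313 with an estimated correlation). Over all genes 2 of them rose. Trem2, a receptor of phagocytes, rose from 4.33 ± 3.43 to 33.0 ± 16.7 CPM (2.92 ± 0.48 SE, adjusted p = 0.0118; 0.0501 without control 5). Lysozyme Lyz2 rose from 113 ± 60.3 to 623 ± 384 (2.46 ± 0.49, adjusted p = 0.0450), a call lost when any library but control 3, DAAO 4 or DAAO 5 was left out (from 0.0613 to 0.113). Reads of Lyz2 can be shared with its near copy Lyz1. Adjusted over the list alone, 9 members were higher, among them Ctss (2.28) and Cd68 (2.56), and 1 was lower, Cd163 (-0.98, adjusted p = 0.387 over all genes), a receptor of resident macrophages named after its value was seen. The list level per library was -0.63 ± 0.92 in controls and 0.63 ± 0.67 in DAAO (SD, n = 6; exact permutation p = 0.0216, two-sided, adjusted 0.0361). Markers of the other tissues that vary between these libraries stood at medians of 0.46 for 9 fibroblast and connective tissue genes (camera adjusted p = 0.0962, under 0.05 without control 2, 3 or 5 or DAAO 4 or 5, from 0.00478 to 0.0370), with 0.70 without control 2. The median was -0.27 for 10 spinal cord genes (camera adjusted p = 0.698; 0.0342, as higher, without control 2, with a median of 0.75). The 8 neutrophil and marrow markers had a median of -0.70 (camera adjusted p = 0.262; 0.0167 without DAAO 3, with a median of -1.60) and the 6 erythroid markers -0.24 (camera adjusted p = 0.691). Without control 2 these 2 medians turned to 0.09 and 0.24.

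Complement genes had a median of 0.71 over 8 members (camera adjusted p = 3.00e-06; adjusted p = 0.313 with an estimated correlation; median 1.07 without control 2), with 1 higher over all genes and 4 adjusted over the list alone. C4b rose from 80.8 ± 13.7 to 153 ± 20.6 CPM (0.93 ± 0.13 SE, adjusted p = 0.00167); its near copy C4a stood at 0.407 and 1.11, and how reads shared by the 2 genes were assigned is not given in the sources used here. The other 3 were C3ar1 (1.62, adjusted p = 0.0792 over all genes), Serping1 (0.48) and C3 (1.38). The NADPH oxidase list, enzymes that make superoxide, had a median of 0.72 over 8 members (camera adjusted p = 0.00633; adjusted p = 0.465 with an estimated correlation; 0.0535 without control 4), and no member changed by itself or adjusted over the list alone. Its call was also lost with pan-neuronal or fibroblast levels as terms and without controls 2, 4 and 6 (medians from 0.34 to 0.53, adjusted p from 0.0594 to 0.360). Interferon response, cytokine and adhesion, and MHC class II lists had medians of 0.01, 0.24 and 0.24 (camera adjusted p = 0.576, 0.355 and 0.575). With muscle, spinal cord and fibroblast levels as terms the interferon list passed as lower (-0.22, adjusted p = 0.0117).

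Markers of endothelial cells, in which the Cdh5 promoter is active, showed no group change. The 21 endothelial markers had a median of 0.03 and a mean of -0.02 (camera adjusted p = 0.592), and no member passed, the tight junction gene Cldn5 (0.54, adjusted p = 0.310) included. The list level per library was 0.01 ± 0.15 in controls and -0.01 ± 0.28 in DAAO (SD, n = 6; exact permutation p = 0.955, two-sided, adjusted 0.955). The pericyte and vascular smooth muscle list had a median of -0.11 (camera adjusted p = 0.649), and 1 of its 10 members, Cspg4, rose by 0.74 ± 0.16 (SE, adjusted p = 0.0335), a call lost when any library but control 2, control 3, DAAO 4 or DAAO 5 was left out (from 0.0609 to 0.111).

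Antioxidant genes did not change as groups in the main fit. The 22 targets of the transcription factor NRF2 had a median of -0.03 (camera adjusted p = 0.691). The 21 peroxide and superoxide enzymes had a median of -0.06 (camera adjusted p = 0.222, or 0.0443 without control 4, with a median of -0.11). With the fibroblast level as a term, alone or with other tissue levels, the peroxide list passed as lower (medians from -0.16 to -0.11, camera adjusted p from 0.0169 to 0.0258). No member of either list changed, Osgin1 (0.93, adjusted p = 0.364) and Glrx (-0.42, adjusted p = 0.364) included, nor did the 6 tested members of the list of mouse D-amino acid and hydrogen peroxide enzymes (median 0.00, camera adjusted p = 0.641). The hypoxia, integrated stress, endoplasmic reticulum stress, p53 and apoptosis lists had medians of 0.00, 0.02, 0.17, 0.13 and 0.14 (camera adjusted p = 0.798, 1, 0.151, 0.301 and 0.112), with no member changed. Adjusted over the list alone 1 apoptosis gene passed, Bcl2l11 (0.80, adjusted p = 0.0835 over all genes), and endoplasmic reticulum stress passed without control 2 or DAAO 2 (0.0467 and 0.0182). Heat shock genes had a median of -0.31 over 11 members (camera adjusted p = 0.000322; adjusted p = 0.313 with an estimated correlation), with Hsp90aa1 (-0.48) and Hsph1 (-0.51) passing only adjusted over the list alone. The level of that list per library was low in DAAO 1, 2 and 3 (-0.34, -0.51 and -0.32). In DAAO 4, 5 and 6 (0.15, 0.17 and 0.02) it lay within the control range (-0.03 to 0.23).

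Metabolic lists lay lower in DAAO by small amounts. Cholesterol synthesis had a median of -0.30, negative in 18 of 19 members (camera adjusted p = 3.89e-08; adjusted p = 0.313 with an estimated correlation). The tricarboxylic acid cycle had a median of -0.21, negative in all 16 (camera adjusted p = 7.03e-06; adjusted p = 0.313 with an estimated correlation). No member of either passed over all genes, and 5 of each passed adjusted over the list alone, namely Msmo1 (-0.51), Hmgcs1 (-0.56), Cyp51 (-0.48), Sc5d (-0.42) and Insig1 (-0.40), and Pdhb (-0.39), Dld (-0.36), Ogdh (-0.32), Idh3b (-0.27) and Dlat (-0.32). Insig1 and Dlat were named after their values were seen. Nuclear subunits of respiratory complex I and of complexes II to V had medians of -0.22 and -0.18 (camera adjusted p = 4.03e-05 and 4.71e-05; adjusted p = 0.643 with an estimated correlation for each), and mitochondrially encoded subunits a median of -0.38 (camera adjusted p = 0.00126; adjusted p = 0.643 with an estimated correlation), with no member changed. Both nuclear lists lost their call without control 2 (medians -0.08 and -0.07, adjusted p = 0.0995 for each) and the mitochondrially encoded list without control 6 (-0.20, adjusted p = 0.0988). Without control 6 the complex I median was -0.13. Without both libraries the nuclear medians were 0.0822 and 0.0298 (camera adjusted p = 0.358 and 0.813).

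**Figure D4:**
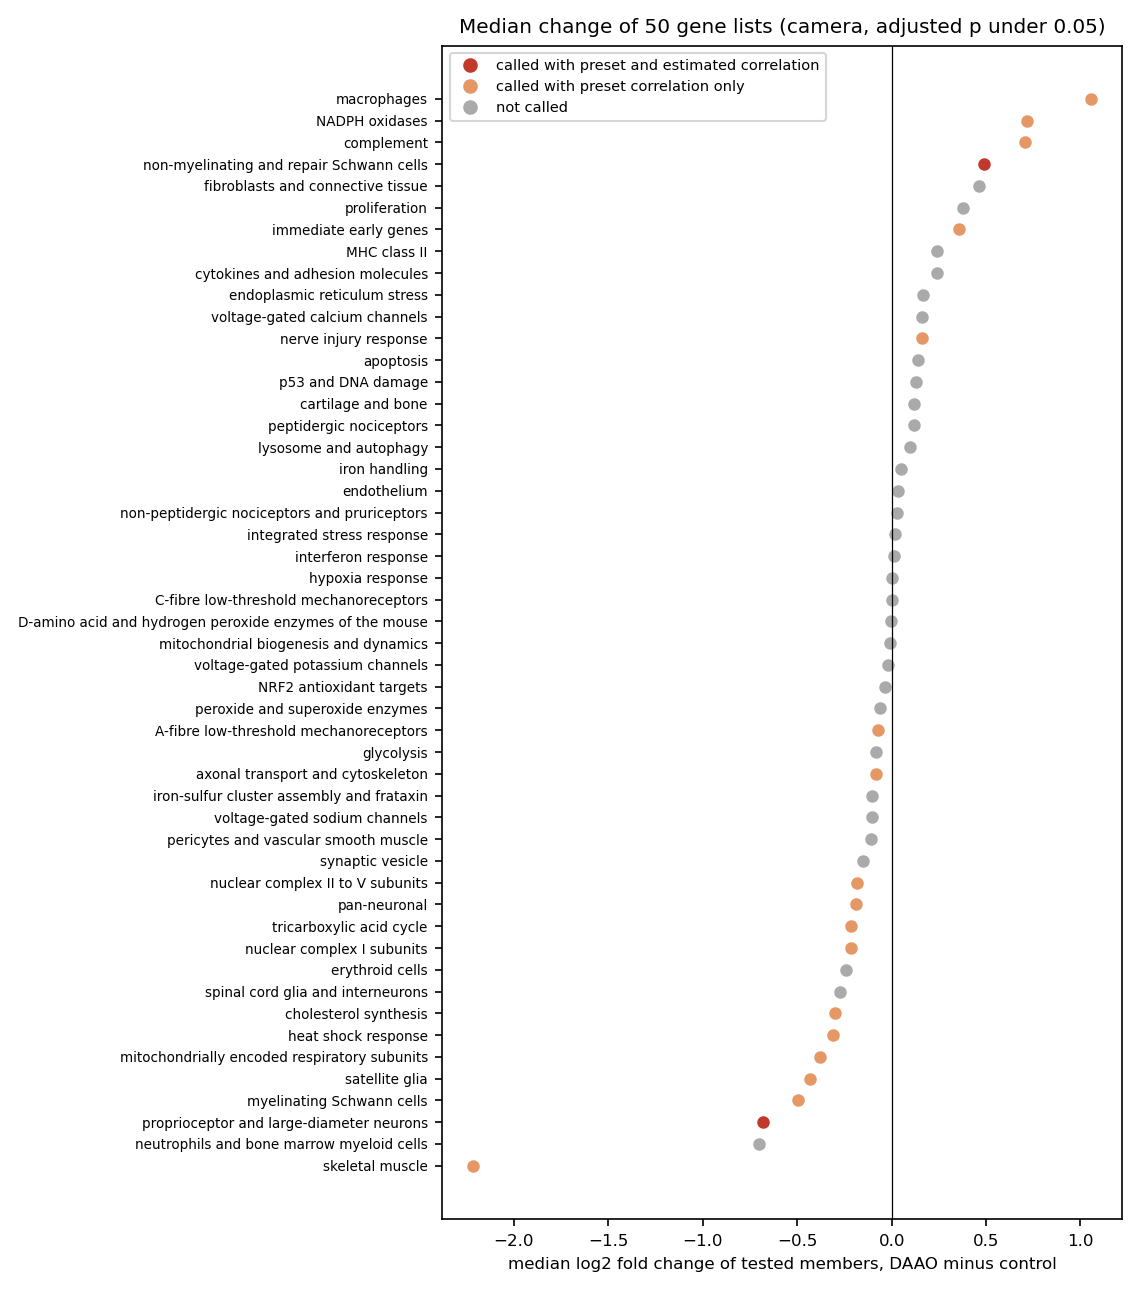
Median log2 fold change of the tested members of each of 50 gene lists (horizontal axis, DAAO minus control), coloured by the camera call. The proprioceptor list (-0.68) and the repair Schwann cell list (0.49) are the 2 called with both the preset and the estimated correlation.

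In all, 19 of 50 lists changed by camera, 6 higher and 13 lower. Only the proprioceptor and repair Schwann cell lists kept their call with an estimated correlation. The remaining lists did not pass: glycolysis -0.08, iron-sulfur cluster assembly -0.10, mitochondrial biogenesis and dynamics -0.01, lysosome and autophagy 0.10, proliferation 0.38, iron handling 0.05, and cartilage and bone 0.12 (medians; camera adjusted p = 0.216, 0.125, 0.222, 0.114, 0.169, 0.641 and 0.989). Leaving out 1 library brought 3 of these under 0.05, glycolysis without control 5 (0.0309, median -0.14), iron-sulfur cluster assembly without control 5 or DAAO 3 (0.0249 and 0.0431, medians -0.18 and -0.14) and lysosome and autophagy without DAAO 2 (0.0306). Of the lysosomal genes Ctsd (0.55, adjusted p = 0.0932) passed adjusted over the list alone. The sign of the median or mean differed from the direction of the test for endothelium, pericytes, cartilage and bone, spinal cord, NRF2 targets, integrated stress and hypoxia, none of which passed. Gapdh, in the glycolysis list, shares sequence with many pseudogenes and its counts are uncertain. Part of the counts is also uncertain for Vamp1, Vstm2b, Jun, Junb, Gadd45a, Cyp51, Idh3b and Gapdh, which overlap another tested gene on the other strand. Lymphocyte and adipocyte lists had 3 and 2 tested members, too few for the test, and none of these changed.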

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

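Of the tests below, those chosen only after the result was seen were the 2 tests per library with tissue levels as terms, the macrophage member median with spinal cord and fibroblast levels as terms, the tests of other sensory neurons, of blood and marrow and of controls 2 and 6, and the count of splits for the macrophage list. Bootstrap ranges below resampled genes, not libraries, so they do not measure the spread between libraries. A library was singled out where its gap to the nearest other library of its group was large against the range of the group, by Dixon's test. Of 270 groups tested 18 gave such a library, and chance alone gives 13.5 at 1 in 20.

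Control 2 stood low in the levels of C-fibre mechanoreceptor (-0.63), peptidergic (-0.84) and non-peptidergic (-0.85) neuron markers and of potassium channels (-0.78), each a mean centred log2 level. Control 2 also stood apart in log2 CPM of Runx3 (1.46), Osgin1 (2.63), Nid2 (3.87) and Ogdh (7.91). The endothelial level of control 3 was 0.30, above the other controls, and the peroxide enzyme level of DAAO 3 was 0.18, above the other DAAO libraries. The log2 CPM of Btc were -3.21 in control 6, those of C3ar1 0.24 in control 4 and those of Cldn5 and Ctsd 3.85 and 8.04 in control 5, each the lowest of its group. In DAAO, Cdh12 was lowest in DAAO 6 (-2.12), C4a in DAAO 3 (-3.21) and Bcl2l11 in DAAO 5 (2.83), and Osgin1 was highest in DAAO 3 (2.90).

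The proprioceptor list was lower in DAAO. A lower share of all sensory neurons as the whole cause was argued against. The 54 markers of other sensory neurons and of all neurons had a median log2 fold change of -0.0180 (bootstrap over markers -0.07 to 0.04). The A-fibre and pan-neuronal lists among them ranked lower. Per library, the proprioceptor list minus 3 other sensory neuron lists was lower in DAAO (-0.98 ± 0.17 SE, exact permutation p = 0.00216, two-sided, adjusted 0.00722). Skeletal muscle carried into control ganglia as the whole cause was argued against per library, where the difference with the muscle level as a term was -0.73 ± 0.13 (SE; permutation p = 0.00433, two-sided), although the member median with that term, -0.62, had a bootstrap range of -0.90 to -0.12 that left it open over members. In 1 of 100 splits, the real one, the camera p was as small (6.38e-13; smallest of the others 2.19e-09). The list was also called in 30 of the other splits, with larger p-values. So small a p was rare among the splits run. The count makes no allowance for the number of lists tested, so chance was not excluded by it. A loss of proprioceptors or other large-diameter neurons, or of their transcripts, with the genotype may remain, as a hypothesis found and tested on the same data. Loss of cells and loss of transcripts were not told apart.

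The macrophage list was higher in DAAO by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.313). Blood or marrow as the whole cause was argued against, although erythroid cells were not tested per library. Over 14 neutrophil and erythroid markers the median was -0.52 (bootstrap over markers -0.70 to -0.22). Without control 2 the medians of the 2 lists were 0.09 and 0.24. Per library, the macrophage minus neutrophil level was higher in DAAO (1.71 ± 0.38 SE, exact permutation p = 0.00433, two-sided, adjusted 0.00866). Spinal cord, root and connective tissue as the whole cause was argued against per library (0.69 ± 0.14 SE with both levels as terms; permutation p = 0.00216, two-sided, the smallest possible), while the member median of 0.60 with those terms had a bootstrap range of 0.31 to 0.96 and cannot be told apart from a partial effect of these tissues. As small a camera p (4.71e-14) came in 6 of 100 splits, the real one included, with 8.31e-23 the smallest of the others, so chance cannot be excluded for this list by that test. More phagocytes in the ganglia of DAAO mice may be a candidate explanation that stays open.

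The nuclear respiratory subunits were lower in DAAO, with a median of -0.20 over 74 subunits. Their 2 lists did not pass camera with an estimated correlation (adjusted p = 0.643 for each). Controls 2 and 6 had the highest control levels of complex I (0.63 and 0.49) and of complexes II to V (0.60 and 0.38). Leaving them out therefore had to lessen the fall. Without them the median was 0.0591 (bootstrap -0.02 to 0.14), so these 2 libraries are a candidate explanation of the fall. What sets them apart was not tested, and no biological explanation was tested.

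Sex was argued against as the cause of the calls, since 122 of the 128 genes passed with the Y-linked level as a term. As many genes came in 2 of 100 splits, the real one included (128, highest other 210). As many 2-fold changes also came in 2 of 100 (73, highest other 142). Such counts were rare among the splits run, but another split gave more, so chance was not excluded for either count. As many lists came in 29 of 100 splits (19; highest other 27), so chance cannot be excluded for the count of lists. For the repair Schwann cell list 1 of 100 splits, the real one, gave a camera p as small (3.12e-09; smallest of the others 0.000653). That list was called in 6 of the other splits. So small a p was rare among the splits run, but the number of lists tested was not allowed for, so chance was not excluded. The split with 210 genes set controls 1, 4, 5 and 6 with DAAO 4 and 5 against the rest and shared 0 genes with the 128. It called 24 lists by camera, with the smallest adjusted p for macrophages (4.15e-21), fibroblasts (3.53e-13) and pan-neuronal (4.18e-12). Cholesterol synthesis (4.35e-08), complement and immediate early genes (8.67e-08 for each) were also called. The proprioceptor and repair Schwann cell lists were not called in it (camera adjusted p = 0.0599 and 0.263). This split points to a structure of the samples that crosses the groups.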

How the results depend on the processing

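The tests chosen only after the result was seen were the terms for spinal cord and fibroblast levels and the fits without controls 2 and 6 or 2, 4 and 6. All 128 genes kept their sign in each fit that tested them; 1 was not tested with at least 1 CPM in 6 libraries and 4 not among protein-coding genes only. Counts are given as genes changed, higher, lower and at least 2-fold, against 128, 86, 42 and 73. They were 370, 227, 143 and 181 with DESeq2, which kept all 128, 307, 178, 129 and 110 with limma-voom and sample weights, and 316, 226, 90 and 139 with the erythroid level as a term. Changed, higher and lower were 248, 165 and 83 with 1 surrogate variable and 73, 54 and 19 with muscle, spinal cord and fibroblast levels as terms. With the muscle level alone 23 were lower. Without controls 2 and 6 the counts were 648, 330, 318 and 171, and without controls 2, 4 and 6 changed, higher and lower were 230, 137 and 93. Library totals without composition factors gave 97 higher and 29 lower. At an adjusted p under 0.01 48 genes changed and at 0.1 226 did, and glmTreat against a log2 change of 0.5 called 40. Leaving out 1 library gave 61 to 322 changed, 47 to 204 higher, 14 to 118 lower, 49 to 135 at least 2-fold and 17 to 23 lists. Genes changed moved by over 1.5 times without control 1 (80), 2 (322) or 5 (77) or DAAO 1 (78), 2 (65), 3 (73) or 6 (61), and genes lower also without control 3 (25) or 4 (25). Against 19 lists, 2 were called with camera's estimated correlation and 4 by fry's directional test, of which apoptosis was not among the 19. Of the 19 lists 14 kept their call with the pan-neuronal or the fibroblast level as a term, both ending those of the pan-neuronal, A-fibre, axonal transport, NADPH oxidase and immediate early lists. The loss of the pan-neuronal call with its own level as a term was fixed in advance. Apart from single libraries left out, calls of mitochondrially encoded and complex I subunits were lost in 3 alternatives each, sample weights among them, complexes II to V in 2 and skeletal muscle in 3. Except without controls 2, 4 and 6, the muscle losses came with the muscle level itself as a term, so they were fixed in advance. Calls were gained by neutrophil, fibroblast and synaptic vesicle lists in 7 alternatives each, calcium channels in 5, erythroid in 4, peroxide enzymes and potassium channels in 3, iron-sulfur assembly in 2, and lysosome, sodium channel, peptidergic, C-fibre and interferon lists in 1. The interferon median reversed to -0.22 (adjusted p = 0.0117, lower) with muscle, spinal cord and fibroblast levels as terms; the complex I median reversed to 0.0822 without controls 2 and 6 and to 0.0385 without controls 2, 4 and 6, and that of complexes II to V to 0.0298 without controls 2 and 6. Other than by the libraries left out, the cause was not tested.

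Whether the replicate numbers pair the libraries stayed open. Of 6 pairs 2 had a correlation of deviations above 0.1 (range -0.0807 to 0.215), and 5 of 12 libraries correlated best with their own number. These values were not compared with chance. With the number as a replicate block 187 genes changed, 144 higher, 43 lower and 114 at least 2-fold, and 21 lists. At this depth and spread a 1.5-fold change was called in 11.9% of simulated genes, so many small changes would be missed.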

Other observations

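All tests of gene families here were chosen only after the result was seen. Several genes of the extracellular matrix rose, and 4 gene families were tested with camera, adjusted over the 4. Of 41 collagen genes 4 rose, Col5a1, which overlaps another gene on the other strand (1.38 ± 0.18 SE, adjusted p = 0.00106), Col5a2 (1.32 ± 0.17, adjusted p = 0.000844), Col18a1 and Col27a1 (1.69, adjusted p = 0.0146; 0.0518 without control 5), and the family ranked above other genes (adjusted p = 1.89e-09; adjusted p = 0.0514 with an estimated correlation). The list of 9 fibroblast and connective tissue markers, some of them collagens, had a median of 0.46 (camera adjusted p = 0.0962) and was called in 12 of 33 alternatives. With the fibroblast level as a term these 4 collagens had log2 fold changes of 1.26, 1.16, 1.48 and 1.86 and still passed, and a part of connective tissue in the rank of the family stays open. Of 23 basement membrane genes 4 rose, Col18a1, Hspg2 (0.91), Nid1 (0.74) and Nid2 (0.79), with an adjusted p of 7.41e-08 for the family (adjusted p = 0.0514 with an estimated correlation). The call of Hspg2 was lost without control 1, 5 or 6 or DAAO 1, 2, 3 or 6 (from 0.0584 to 0.103), that of Nid1 when any library but control 2, control 3 or DAAO 5 was left out (from 0.0520 to 0.112) and that of Nid2, which overlaps Rtraf, when any but control 2 or DAAO 5 was (from 0.0538 to 0.115). These genes were chosen after their values were seen.

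Of 13 matrix metalloproteinase genes 3 rose, Mmp12, Mmp17 (1.38, adjusted p = 0.000589) and Mmp14 (0.95, adjusted p = 0.0254), the last lost without control 1, 3, 4 or 5 or DAAO 1, 2, 3 or 6 (from 0.0571 to 0.0878). The family ranked above other genes with both correlations (adjusted p = 7.41e-08; adjusted p = 0.00390 with an estimated correlation). The families were chosen because some of their genes had been called, so these ranks restate those calls. Without the called genes the collagen, basement membrane and metalloproteinase families ranked higher with the preset correlation (adjusted p = 0.00141, 0.0150 and 0.0321) but did not pass with an estimated correlation (adjusted p = 0.265, 0.273 and 0.210), so a rise of matrix expression with the genotype cannot be told from these tests. Among 23 vacuolar proton pump genes Atp6v0d2 and Tcirg1 (0.98, adjusted p = 0.00957) rose, but the family did not (adjusted p = 0.809), which argued against a general rise of pump subunits.

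Gapdh ranged from 3.99 to 361 CPM over the controls and from 5.36 to 91.7 over the DAAO libraries. The high values were those of control 2 (287), control 6 (361) and DAAO 2 (91.7), and no other control exceeded 8.19. Controls 2 and 6 also had the highest mitochondrial shares (7.44% and 7.65%). The handling of Gapdh pseudogenes in the counting is not given in the sources used here, and the cause of these differences between libraries was not tested. Of the 12 libraries 5 held both Xist and Y-linked transcripts, 4 Xist alone and 3 Y-linked transcripts alone.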
